A study of Mus musculus with 4 samples.

How the data were processed

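Single-cell suspensions of whole kidney had been sorted for live cells and sequenced with a droplet 3′ kit, per the labels, in 2 mutant and 2 wild-type mice. The deposited files hold raw UMI counts per gene and cell barcode, made with Cell Ranger 7.0.0 for the mutants and 7.1.0 for the wild types per the file headers. The mm10 build is per the submitters' notes, and the annotation release and settings are not given in the sources used here. Software version and group coincide. The 4 libraries share a list of 32285 genes and held 11744, 10460, 7595 and 7242 barcodes (mutant 1, mutant 2, wild type 1, wild type 2). Ages, litters and processing days are not given in the sources used here.

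Barcodes with at least 200 genes, at least 500 UMIs and at most 50% mitochondrial UMIs were kept. Scrublet, run per library in scanpy 1.11.5, called 300, 250, 126 and 141 doublets, which were removed. This left 30242 of 37041 barcodes, with medians of 1663, 2178.5, 1946.5 and 2299 genes per cell. Barcodes over 50% mitochondrial made up 16.8%, 13.3%, 24.1% and 11.2%. Counts were normalized to a common total and log-transformed, and 2000 variable genes, 30 principal components and 15 neighbours gave 32 Leiden clusters at resolution 1 (leidenalg 0.10.2, seed 1). Each cluster took the name of the marker list with the highest level over the other clusters, if at least 3 markers were detected in at least 10% of its cells. A cluster stayed unnamed if its 10 most raised genes held more markers of another type, which was so for 3 clusters, or if it was shallow and they held none of its own. No correction for free RNA or for library effects was applied, and clusters were formed without integration of libraries.

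UMIs were summed per library and class, so that the mouse was the unit of replication. The 6 classes with the most cells in their smallest library, and at least 50 there, were tested: proximal tubule, T cell, B cell, thick ascending limb, distal convoluted and connecting tubule, and monocyte. Genes were filtered with filterByExpr, scaled with TMM and tested with the quasi-likelihood F test of edgeR 4.0.16 (R 4.3.3), with Benjamini-Hochberg adjustment within the class and a threshold of 0.05. DESeq2 1.42.0 was run beside it. Lists of genes with at least 5 members tested were compared with camera and fry (limma 3.58.1) at a preset correlation of 0.01 and at an estimated one, and the marker lists were tested as a separate family. Class shares were tested with edgeR on cell numbers and with exact permutation. The share of mitochondrial UMIs was compared by exact permutation, and the difference between classes as an interaction with the library as a block.

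Genes were named by a rule. Of genes past the threshold with both mutant values above or both below the wild-type values and a mean of at least 30 CPM, it took the 8 largest rises and falls in the proximal tubule and T cells and the 3 largest in other classes, passing over predicted genes. It also took up to 4 members of each list with the smallest p, and all mitochondrial genes. Of these, 47 genes past the threshold and 27 not past it were followed through the alternatives. C1qa, C1qb, C1qc, Nos1, Slc12a1, Egr1 and Mctp1 are given as well for particular questions, and each was chosen after its values were seen where the rule did not name it. Groups, tests, lists, the naming rule and most alternatives were fixed before the data were examined. The alternatives were other scaling (RLE, library totals), no filter on low counts, a replicate block, other limits on mitochondrial share and UMIs, doublet calls kept, mitochondrial genes left out, and each library left out. The replicate block paired the libraries by the number in their titles, and the sources used here give no other basis for that pairing. Positions are from GENCODE M21.

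The edgeR test was tested on simulated data with the same depth and the dispersion trend of each class, with 200 changed genes of at least 50 counts. Each gene took the trend in place of its own dispersion, and genes were drawn independently. Libraries of a group shared the same means, unlike the real ones, so the rates describe a simpler case than these data. Of genes changed 4-fold it found 81%, 72%, 62%, 99%, 96% and 84% in the 6 classes in the order above, and of genes changed 2-fold 10%, 7%, 4%, 39%, 18% and 13%. False calls numbered 3, 3, 0, 7, 2 and 2. A zero count was bounded with a floor of 3 counts over the group, or per library for shares of cells. Intervals are exact at 95%, except that of the odds ratio, which is approximate. The unnamed cells and predicted genes were left out of the named results.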

Results

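Kidney cells of mice with a point mutation in TrnE, the mitochondrial gene for the transfer RNA of glutamate, were compared with those of wild-type C57BL/6J mice by droplet single-cell RNA sequencing. 2 mutant libraries, with mutation loads of 79% and 76% per the labels, stood against 2 wild-type libraries. Groups and loads follow the labels, although the deposited name of wild-type library 1 resembles that of a mutant and the name of mutant library 1 carries a different number from its load. The genotype of each library could not be checked from the counts. The libraries held 65565948 and 70013861 UMIs for the mutants and 42121175 and 59946996 for the wild types. After filtering, 9477 and 8832 mutant cells and 5644 and 6289 wild-type cells remained, with medians of 4357, 5767.5, 4861 and 6456 UMIs per cell. Group values are the mean ± SD over n = 2 libraries, in CPM (counts scaled to a common library total) of the UMIs summed per library and cell class. Positions are on mm10, and fold changes are mutant over wild type, from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment within each class.

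Macrophages, the resident phagocytes of the kidney, made up 24.3 ± 6.82% of mutant and 7.62 ± 9.50% of wild-type cells (n = 2). The log2 fold change was 1.67 (SE 1.28, adjusted p = 0.942 by edgeR), and the exact permutation test gave p = 0.333, the smallest that 2 against 2 allows. Cells of the proximal tubule, which reabsorbs most of the filtrate, made up 21.0 ± 9.76% of mutant and 44.8 ± 21.1% of wild-type cells (log2 fold change -1.09, SE 1.26). T cells made up 22.9 ± 13.3% and 12.1 ± 1.40%. None of the 13 named classes or the unnamed cells passed the edgeR test, 0 also at an unadjusted p under 0.05. Wild-type library 2 stood apart from the other 3 libraries. Its macrophages made up 0.906% of cells (95% exact Clopper-Pearson interval 0.687 to 1.17%), against 14.3% in wild-type library 1, and its proximal tubule 59.8%, against 14.1 to 29.9% in the others. Its endothelium made up 0.572% against 7.77 to 13.7%, its B cells 14.3% against 1.85 to 4.14%, and its antibody-secreting plasma cells 3.93% against 0.372 to 0.528%. Without wild-type library 1, 6 classes passed, 4 higher and 2 lower in the mutants. Intervals here and elsewhere cover counting error only.

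**Figure D1:**
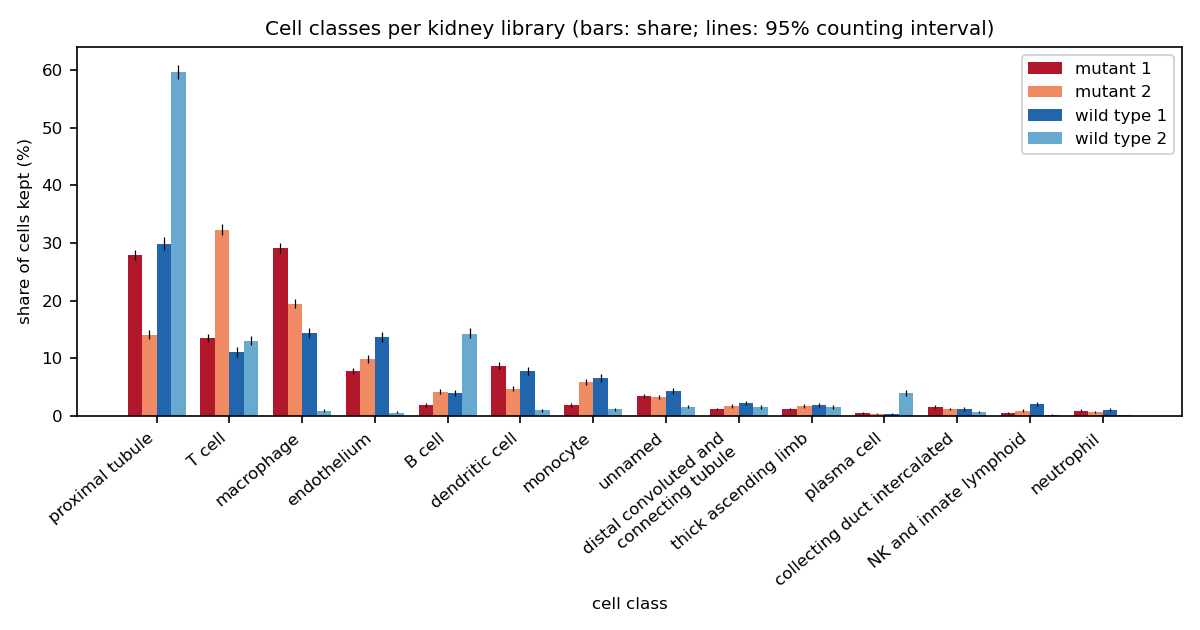
Share of the cells kept (%, vertical axis) in each cell class (horizontal axis) in the 2 mutant and 2 wild-type libraries. Bars are shares and lines 95% counting intervals. Macrophages lay at 29.1% and 19.5% in the mutants and at 14.3% and 0.906% in the wild types.

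In the proximal tubule, 99 of 13273 genes passed the threshold of 0.05, 89 higher and 10 lower in the mutants. DESeq2 called 144. Among genes with a mean of at least 30 CPM, the 8 with the largest rises are given here. Genes at lower levels rose more, among them the chemokines Ccl12 (log2 fold change 4.25) and Ccl8 (3.77). H2-Ab1 (ENSMUSG00000073421, chromosome 17, 34257689 to 34269419), a chain of the class II antigen-presenting complex, rose from 68.8 ± 22.4 to 418 ± 73.3 CPM (log2 fold change 2.74, SE 0.53, adjusted p = 0.0365 by edgeR). H2-Eb1 (ENSMUSG00000060586, chromosome 17, 34305867 to 34316674), another class II chain, rose from 74.0 ± 23.2 to 349 ± 111 CPM (log2 fold change 2.37, SE 0.52, adjusted p = 0.049 by edgeR). Tyrobp (ENSMUSG00000030579, chromosome 7, 30413760 to 30417585), the signalling adaptor of myeloid receptors, measured 67.8 ± 32.8 against 10.9 ± 7.73 CPM (log2 fold change 2.75, SE 0.54, adjusted p = 0.0371 by edgeR). Fcer1g (ENSMUSG00000058715, chromosome 1, 171229572 to 171234365), the shared gamma chain of Fc receptors, measured 89.0 ± 49.4 against 15.2 ± 9.72 CPM (log2 fold change 2.65, SE 0.54, adjusted p = 0.0372 by edgeR). Ctss (ENSMUSG00000038642, chromosome 3, 95526786 to 95556403), a protease that trims antigens, measured 78.6 ± 29.2 against 16.2 ± 11.1 CPM (log2 fold change 2.38, SE 0.52, adjusted p = 0.049 by edgeR). Ifitm3 (ENSMUSG00000025492, chromosome 7, 141009586 to 141010770), an interferon-induced membrane protein, measured 53.6 ± 2.69 against 12.6 ± 6.60 CPM (log2 fold change 2.24, SE 0.45, adjusted p = 0.0371 by edgeR). AW112010 (ENSMUSG00000075010, chromosome 19, 11047612 to 11055808), an inducible immune transcript, measured 57.9 ± 33.2 against 16.7 ± 2.40 CPM (log2 fold change 2.04, SE 0.45, adjusted p = 0.0493 by edgeR). Fos (ENSMUSG00000021250, chromosome 12, 85473890 to 85477273), an immediate early transcription factor, measured 76.3 ± 62.5 against 13.4 ± 7.0 CPM (log2 fold change 2.70, SE 0.50, adjusted p = 0.034 by edgeR).

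Each of these 8 proximal tubule genes was higher in both mutants than in both wild types, which the naming rule required. The 10 genes lower in the mutants had mean levels under the minimum of 30 CPM for naming. Of the 89 higher genes, 70 (78.7%, exact interval 68.7 to 86.6%) had over 10 times their tubule CPM in the pooled immune classes, against 6.94% of all genes tested. Macrophage marker genes were higher as a set (median log2 fold change 2.81, 11 of 11 positive), as were T cell markers (1.92, 13 of 13), each with a camera adjusted p = 0.482 with an estimated correlation. Endothelium markers (1.22, 11 of 11, adjusted p = 0.483 with an estimated correlation) and intercalated cell markers of the collecting duct (0.96, 4 of 6, adjusted p = 0.482 with an estimated correlation) were higher as well, as were monocyte (1.5, 6 of 8) and NK markers (2.06, 5 of 5; adjusted p = 0.482 and 0.483 with an estimated correlation). The complement transcripts C1qa, C1qb and C1qc, which macrophages express, together reached 459 and 184 CPM in mutant proximal tubule and 82.2 and 8.14 CPM in wild-type. The count of genes depended on single libraries: 231 passed without mutant library 1, 1181 without wild-type library 1 and 0 without wild-type library 2 (edgeR, 733 at an unadjusted p under 0.05). It also depended on settings: 1 passed with doublet calls kept, 0 with library totals in place of TMM (edgeR, 1225 at an unadjusted p under 0.05), and 3 of 12344 with the genes dominated by immune classes left out. In that last setting Fos kept a log2 fold change of 2.74 (edgeR adjusted p = 0.0543). Of the 8 genes, 7 passed with the replicate block, 5 with RLE, and 5 and 7 at mitochondrial shares of at most 25% and 80%. With mitochondrial genes left out 4 passed, and without the shallow proximal tubule cluster 2. With doublet calls kept or library totals 0 of the 8 passed, whereas all 8 passed with DESeq2, no filter or 1500 UMIs per cell. Without wild-type library 2 the 8 genes had log2 fold changes of 1.63 to 3.12 and adjusted p of 0.233 to 0.564 by edgeR. H2-Ab1, H2-Eb1 and Fos also missed the threshold without mutant library 1 (edgeR adjusted p up to 0.337). So did H2-Ab1, H2-Eb1 and AW112010 without mutant library 2 (up to 0.96), and Fos and AW112010 without wild-type library 1 (0.0569 and 0.0611). The log2 fold change was 1.63 for Fos without mutant library 1, 1.15 for AW112010 without mutant library 2, and 4.04 for Tyrobp, 3.81 for Fcer1g and 3.63 for Ctss without wild-type library 1.

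The other 19 higher genes of the proximal tubule, those without such an excess in the immune classes (no other class was compared), included the 8 given here and the immediate early genes Fos, Egr1 and Klf4. Nupr1 and Mgp, another of the 19, were also among the 10 most raised genes of an unnamed cluster with fibroblast markers. This cluster held 73 and 27 cells in the mutants and 17 and 1 in the wild types. Clu was among the 10 most raised genes of the distal convoluted and connecting tubule cluster and of an unnamed cluster with principal cell markers. In the pooled immune classes Cdkn1a and Nupr1 measured 39.7 and 27.2 CPM, above their mutant tubule levels though under the 10-fold cut. The others of the 8 measured 0.227 to 13.4 CPM there. Gdf15 (ENSMUSG00000038508, chromosome 8, 70629393 to 70632456), a cytokine released under mitochondrial stress, measured 37.6 ± 29.7 against 9.07 ± 3.42 CPM (log2 fold change 2.24, SE 0.45, adjusted p = 0.0372 by edgeR). Atf5 (ENSMUSG00000038539, chromosome 7, 44812256 to 44816658), a transcription factor of the mitochondrial stress response, measured 17.0 ± 9.87 against 4.68 ± 0.911 CPM (log2 fold change 2.04, SE 0.43, adjusted p = 0.0434 by edgeR). Nupr1 (ENSMUSG00000030717, chromosome 7, 126623249 to 126630861), a stress-induced chromatin protein, measured 8.06 ± 4.77 against 1.30 ± 0.916 CPM (log2 fold change 2.89, SE 0.63, adjusted p = 0.049 by edgeR). Cdkn1a (ENSMUSG00000023067, chromosome 17, 29090976 to 29100727), the p53 target that halts the cell cycle, measured 13.9 ± 11.8 against 2.63 ± 0.249 CPM (log2 fold change 2.58, SE 0.52, adjusted p = 0.0371 by edgeR). Clu (ENSMUSG00000022037, chromosome 14, 65968483 to 65981547), a secreted chaperone of injured tubules, measured 8.46 ± 1.51 against 1.46 ± 0.180 CPM (log2 fold change 2.75, SE 0.47, adjusted p = 0.0276 by edgeR). Fgg (ENSMUSG00000033860, chromosome 3, 83007724 to 83015049), a fibrinogen chain made in injured tubules, measured 58.3 ± 0.255 against 20.5 ± 1.45 CPM (log2 fold change 1.72, SE 0.35, adjusted p = 0.0407 by edgeR). C3 (ENSMUSG00000024164, chromosome 17, 57203970 to 57228136), the central complement component, measured 16.1 ± 1.05 against 5.72 ± 0.450 CPM (log2 fold change 1.69, SE 0.37, adjusted p = 0.0493 by edgeR), and Cfi (ENSMUSG00000058952, chromosome 3, 129835884 to 129875332), a complement protease, measured 35.9 ± 15.7 against 9.96 ± 0.482 CPM (log2 fold change 2.08, SE 0.40, adjusted p = 0.0365 by edgeR). All 8 were higher in both mutants. With immune-dominated genes left out they kept log2 fold changes of 1.74 to 2.96, but Clu alone passed (edgeR adjusted p = 0.0455, the others 0.0543 to 0.0723), and with doublet calls kept or library totals none of the 8 passed. Calls were lost in other settings as well. Of the 24 list members followed in this class, these 8 among them, 15 passed with mitochondrial genes left out and 17 without the shallow cluster. With RLE 21 passed, and at a mitochondrial share of at most 25% 22. Without wild-type library 2 none passed (adjusted p 0.284 to 0.567, log2 fold changes 1.40 to 2.65), and Gdf15, Atf5, Nupr1 and Cdkn1a also missed without mutant library 1, where their log2 fold changes were 1.23, 1.40, 2.17 and 1.39. Without mutant library 2, in edgeR, Fgg, C3 and Cfi missed (adjusted p = 0.357, 0.309 and 0.353), Fgg missed without mutant library 1 as well (0.117), and Gdf15 and Cdkn1a missed without wild-type library 1 (0.0656 and 0.0531).

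**Figure D2:**
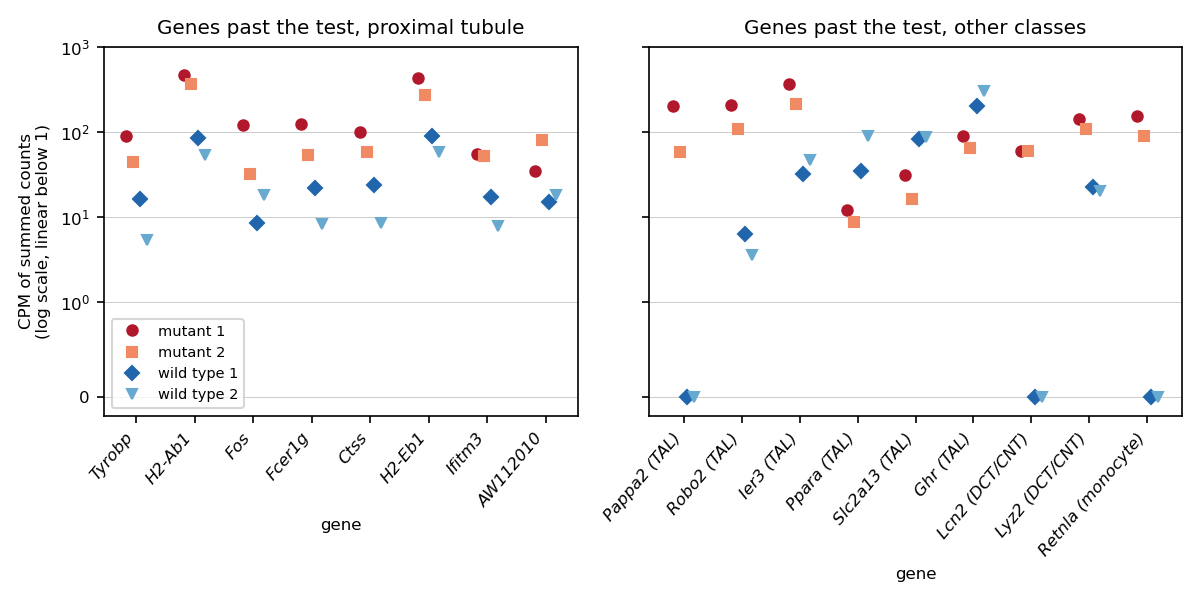
CPM of summed counts (vertical axis, log scale, linear below 1) of the genes named by the fixed rule (horizontal axis) in each library. Points are single libraries, 2 mutant and 2 wild-type. Left, proximal tubule; right, thick ascending limb (TAL), distal convoluted and connecting tubule (DCT/CNT) and monocytes. H2-Ab1 averaged 418 CPM in the mutants and 68.8 in the wild types.

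Of 33 gene lists tested with camera in the proximal tubule, 24 were higher in the mutants and 0 lower at the preset correlation of 0.01. Antigen presentation genes, which load peptides for T cells, had a median log2 fold change of 1.61 (15 of 15 positive); 4 rose over all genes tested and 14 adjusted over the list alone (list adjusted p = 1.79e-23, adjusted p = 0.274 with an estimated correlation). Interferon response genes had a median of 1.63 (31 of 32 positive), with 3 higher, among them Isg15 and Ifi27l2a, and 16 adjusted over the list alone (4.94e-19, adjusted p = 0.296 with an estimated correlation). Inflammatory chemokines and NF-kB targets, which recruit leukocytes, had a median of 1.73 (21 of 24), with 6 higher, among them Ccl4 and Il1b, and 12 over the list alone (2.96e-17, adjusted p = 0.274 with an estimated correlation); it was the only list called by fry in any class (adjusted p = 0.0369). Tubular injury genes had a median of 1.39 (24 of 25), with 5 higher, among them Clu and Vim, and 13 over the list alone (1.33e-17, adjusted p = 0.274 with an estimated correlation). Vim was among the 70 higher genes dominated by the immune classes. Complement and acute phase genes had a median of 1.72 (11 of 11), with 4 higher and 9 over the list alone (4.11e-16, adjusted p = 0.274 with an estimated correlation). Immediate early genes, which tissue dissociation induces, had a median of 1.34 (21 of 21), with 2 higher and 15 over the list alone (1.33e-17, adjusted p = 0.274 with an estimated correlation). Targets of ATF4 in the integrated stress response, the relay of mitochondrial defects to the nucleus, had a median of 0.66 (25 of 26), with 3 higher and 8 over the list alone (1.13e-08, adjusted p = 0.468 with an estimated correlation). With an estimated correlation 0 lists passed in any of the 6 classes.

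Metabolic lists of the proximal tubule moved less. Proximal tubule transporters, which carry out reabsorption, were not lower as a set (median -0.02, 15 of 31 positive, camera adjusted p = 0.254; 0.0406 without wild-type library 2), nor were gluconeogenesis genes (median -0.01, adjusted p = 0.979) or hypoxia targets (median -0.02, adjusted p = 0.667). Fatty acid oxidation genes, the main fuel pathway of this segment, were higher (median 0.38, 23 of 29 positive, adjusted p = 0.0321; adjusted p = 0.723 with an estimated correlation; without wild-type library 2 the direction turned to lower, with 0.173). Nuclear genes for complex I, the first respiratory complex, were higher in 36 of 36 members (median 0.50, 0 past the gene test, list adjusted p = 2.00e-05, adjusted p = 0.723 with an estimated correlation). Mitochondrial ribosomal protein genes were higher in 76 of 78 (median 0.51, adjusted p = 2.68e-09, adjusted p = 0.723 with an estimated correlation). Both lists missed without wild-type library 2 (camera adjusted p = 0.769 and 0.414). Cytosolic ribosomal protein genes were higher in 79 of 80 (median 0.46, camera adjusted p = 1.42e-05, adjusted p = 0.723 with an estimated correlation). Without wild-type library 2 their median was 0.121. Random lists matched to them on gene length and level had a median of 0.514, and 99.7% of these lists were as high. These random lists could draw the complex I and mitochondrial ribosomal protein genes.

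**Figure D3:**
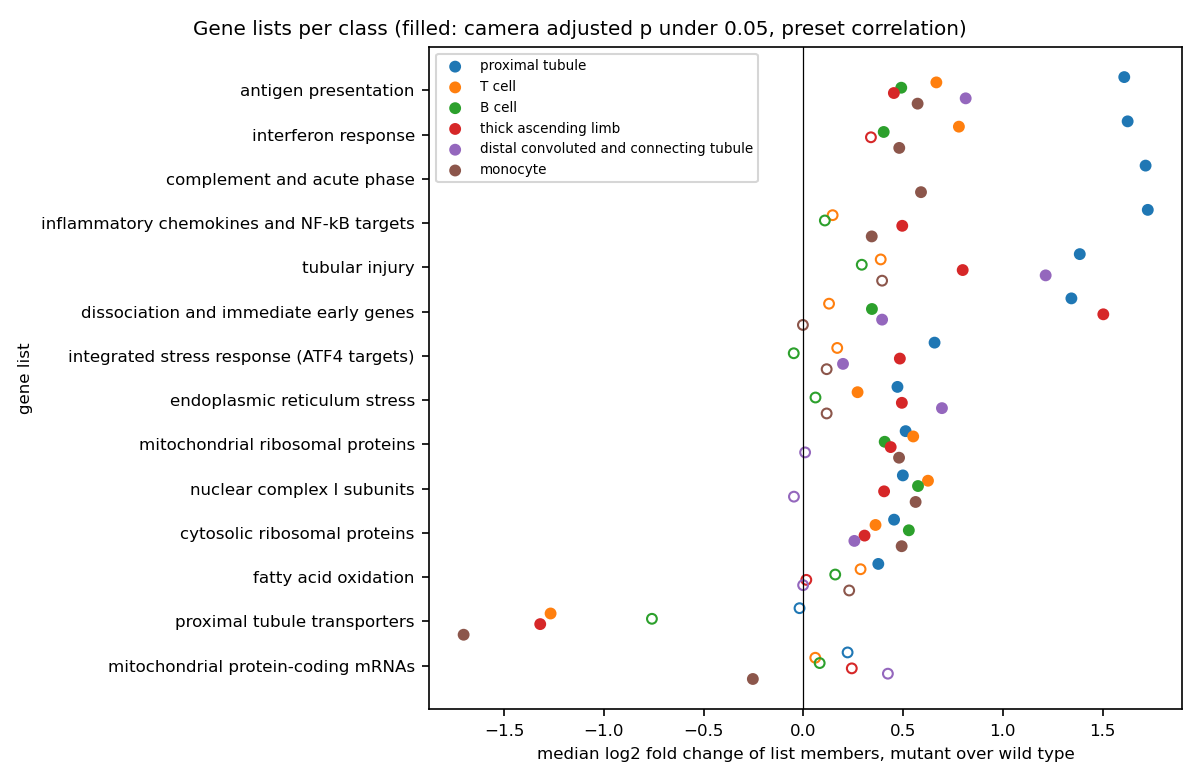
Median log2 fold change of list members, mutant over wild type (horizontal axis), for selected gene lists (vertical axis) in the 6 tested classes. Points are classes; filled points had a camera adjusted p under 0.05 with the preset correlation. The antigen presentation median was 1.61 in the proximal tubule.

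In the thick ascending limb, the salt-reabsorbing segment of the loop of Henle, 39 of 8257 genes passed, 30 higher and 9 lower in the mutants (DESeq2 called 33, 14 of them shared). Robo2 (ENSMUSG00000052516, chromosome 16, 73891839 to 74411825), an axon guidance receptor, showed 159.9 ± 70.6 against 5.00 ± 1.97 CPM, a 35.4-fold rise (log2 fold change 5.15, SE 0.46, adjusted p = 0.00172 by edgeR). Pappa2 (ENSMUSG00000073530, chromosome 1, 158711727 to 158980490), a protease typical of the macula densa, had 221 UMIs in the mutants and 0 in the wild types, so it was at least 61.5-fold higher against a floor of 3 counts over the wild-type group (adjusted p = 0.00957, edgeR). Ier3 (ENSMUSG00000003541, chromosome 17, 35821684 to 35822923), an immediate early gene, showed 289 ± 104 against 39.5 ± 10.6 CPM (log2 fold change 3.00, SE 0.30, adjusted p = 0.00304 by edgeR). Lgals3 (ENSMUSG00000050335, chromosome 14, 47367751 to 47386160), a lectin raised in injured tubules, showed 555 ± 41.9 against 135 ± 15.3 CPM (log2 fold change 2.19, SE 0.24, adjusted p = 0.00448 by edgeR). Ppara (ENSMUSG00000022383, chromosome 15, 85734983 to 85802819), the nuclear receptor that drives fatty acid oxidation, fell from 62.7 ± 38.9 to 10.4 ± 2.43 CPM (log2 fold change -2.45, SE 0.46, adjusted p = 0.0468 by edgeR). Slc2a13 (ENSMUSG00000036298, chromosome 15, 91267696 to 91573261), a myo-inositol transporter, fell from 85.5 ± 3.29 to 23.9 ± 10.8 CPM (log2 fold change -1.70, SE 0.31, adjusted p = 0.0465 by edgeR). Ghr (ENSMUSG00000055737, chromosome 15, 3317760 to 3583492), the growth hormone receptor, fell from 252 ± 71.0 to 78.1 ± 18.2 CPM (log2 fold change -1.54, SE 0.25, adjusted p = 0.0333 by edgeR). Over all genes of this class the log2 fold change fell with gene length (Spearman correlation -0.534). Whether the falls of Ppara, Slc2a13 and Ghr go beyond that trend was not tested. The stress cytokine Gdf15 rose as well, with 67 UMIs against 3 (ratio of pooled CPM 18.7, exact interval 6.11 to 92.7, adjusted p = 0.0406), as did the endoplasmic reticulum factor Manf (1.41, SE 0.24, adjusted p = 0.0383) and the injury receptor Tnfrsf12a (2.70, SE 0.44, adjusted p = 0.0333).

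The macula densa is a plaque of thick ascending limb cells that senses salt and expresses Nos1 and Pappa2. Cells with UMIs of at least 2 of Pappa2, Nos1 and Robo2, a set chosen after its values were seen, numbered 9 of 110 and 4 of 148 in the mutants. In the wild types they numbered 0 of 103 and 0 of 95. A floor of 3 counts per library puts the shares at up to 2.91% and 3.16%, and the exact 95% upper limits are 3.52% and 3.81%. All of these bounds lie above the 2.70% of mutant library 2. The class marker Slc12a1 had 4197 and 4904 UMIs in the mutants and 4785 and 4980 in the wild types, and did not pass (log2 fold change -0.25, adjusted p = 0.700, edgeR). In the thick ascending limb 20 genes passed without mutant library 1, 102 without mutant library 2, 839 without wild-type library 1 and 252 without wild-type library 2. Robo2, Pappa2, Ier3 and Lgals3 passed the edgeR test in each of these, whereas Ppara missed without mutant library 1 (adjusted p = 0.0809) and wild-type library 2 (0.0766). Calls were also lost for Slc2a13 without mutant library 2 (0.106), Ghr without mutant library 1 or 2 (0.0714 and 0.0644), and Gdf15 and Manf without mutant library 1 (0.325 and 0.138). Robo2, Ier3 and Lgals3 also passed with doublet calls kept, with library totals and at a mitochondrial share of at most 80%, whereas Pappa2 missed with doublet calls kept (edgeR adjusted p = 0.0772). Ppara, Slc2a13, Ghr, Gdf15, Manf and Tnfrsf12a missed in all 3 settings (edgeR, 0.0593 to 0.138). Ppara and Slc2a13 missed with RLE (0.0545 and 0.0533), Ppara at 1500 UMIs per cell (0.0581) and Slc2a13 at a mitochondrial share of at most 25% (0.0539). Manf missed in DESeq2 (0.0648), where Ppara, Slc2a13, Gdf15 and Tnfrsf12a had no adjusted p.

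Of 28 lists in the thick ascending limb, 14 were higher and 1 lower. Immediate early genes had a median of 1.5 (18 of 18 positive), with 1 higher over all genes and 14 adjusted over the list alone (7.63e-12, adjusted p = 0.416 with an estimated correlation). Tubular injury genes had a median of 0.80 (14 of 17), with 1 and 7 (9.98e-09, adjusted p = 0.416 with an estimated correlation). Integrated stress response genes had a median of 0.48 (15 of 20), with 1 and 4 (0.00131, adjusted p = 0.627 with an estimated correlation), and endoplasmic reticulum stress genes 0.49 (14 of 17; 0.00279, adjusted p = 0.545 with an estimated correlation; 0.0770 without wild-type library 2). Complex I genes were higher in 36 of 36 (median 0.41, 1.63e-06, adjusted p = 0.416 with an estimated correlation). The injury marker Lcn2 (2.90, edgeR adjusted p = 0.0824), the ATF4 targets Nupr1 (2.06, 0.0721) and Atf5 (1.86, 0.0939), and Ppargc1a, which drives mitochondrial biogenesis (-0.96, 0.11), did not pass.

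In the distal convoluted and connecting tubule, which fine-tunes salt and calcium, 2 of 5353 genes passed, both higher (DESeq2 called 4). Lcn2 (ENSMUSG00000026822, chromosome 2, 32384633 to 32388252), the urinary marker of tubular damage, stood at 60.4 ± 0.113 CPM in the mutants and had 0 wild-type UMIs, at least 19.7-fold higher against 3 counts over the group (adjusted p = 0.0360, edgeR). Lyz2 (ENSMUSG00000069516, chromosome 10, 117277331 to 117282321), lysozyme of myeloid cells, measured 127 ± 24.3 against 21.4 ± 1.51 CPM (log2 fold change 2.69, SE 0.36, adjusted p = 0.0458 by edgeR). Of 24 lists, 8 were higher: tubular injury genes in 16 of 16 members (median 1.22, 1 past the gene test and 8 adjusted over the list alone, 2.58e-24, adjusted p = 0.609 with an estimated correlation), and endoplasmic reticulum stress genes, which include Hspa5 and Manf, in 15 of 15 (median 0.70, 0 and 1, 4.17e-08, adjusted p = 0.816 with an estimated correlation; 0.0519 without wild-type library 2). Markers of collecting duct principal cells were higher in 6 of 6 (median 0.71, adjusted p = 0.558 with an estimated correlation) and proximal tubule markers lower in 10 of 11 (median -0.47, adjusted p = 0.644 with an estimated correlation). Without wild-type library 2 the principal cell markers turned to lower (camera adjusted p = 0.297) and the fall of proximal tubule markers missed (0.746). Complex I genes were not higher (median -0.05, 16 of 36 positive, camera adjusted p = 0.743). In edgeR, Lcn2 and Lyz2 both missed without mutant library 1 (adjusted p = 0.167 and 0.640, 0 genes passing, 138 at an unadjusted p under 0.05) and without mutant library 2 (0.0857 and 0.0789). They also missed with doublet calls kept (0.206 and 0.225), at 1500 UMIs per cell (0.0582 and 0.0781) and with mitochondrial genes left out (0.0547 and 0.0702), and Lyz2 with RLE (0.0551). By contrast, 327 genes passed without wild-type library 1 and 7 without wild-type library 2.

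In monocytes, the circulating precursors of kidney macrophages, 1 of 9267 genes passed (DESeq2 called 2). Retnla (ENSMUSG00000061100, chromosome 16, 48842551 to 48844461), a secreted protein of alternatively activated myeloid cells, measured 124 ± 46.4 CPM in the mutants and had 0 wild-type UMIs, at least 120.4-fold higher against 3 counts over the group (adjusted p = 0.00514, edgeR). It passed without each library in turn, when 18 to 38 genes passed: 31 without mutant library 1, 38 without mutant library 2, 19 without wild-type library 1 and 18 without wild-type library 2. Of 32 lists, 11 were higher and 3 lower. Interferon response genes were higher in 23 of 31 (median 0.48, 0 past the gene test and 0 adjusted over the list alone, 1.82e-05, adjusted p = 0.600 with an estimated correlation), and complex I genes in 36 of 36 (median 0.56, 1.10e-09, adjusted p = 0.600 with an estimated correlation). Proximal tubule transporters were lower in 9 of 10 (median -1.70, 1.99e-10, adjusted p = 0.600 with an estimated correlation), and T cell markers higher in 9 of 9 (median 1.83, adjusted p = 0.454 with an estimated correlation). Macrophage markers were higher in 10 of 11 (median 1.07, camera adjusted p = 6.34e-05, adjusted p = 0.454 with an estimated correlation; 0.0910 without wild-type library 2).

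In T cells 0 of 11870 genes passed in edgeR, 448 at an unadjusted p under 0.05, and DESeq2 called 13. The T cell class joined clusters that the libraries filled unevenly, so tests within the class mix T cell subsets. A cluster with Cd4 and Ctla4 among its most raised genes held 420 of 1276 and 951 of 2854 T cells in the mutants. In the wild types it held 121 of 625 and 545 of 821. In B cells 0 of 9753 passed, 356 at an unadjusted p under 0.05, and DESeq2 called 1. The T cell count rose to 14 without mutant library 2 and 15 without wild-type library 1, and the B cell count to 468 without wild-type library 1 and 11 without wild-type library 2. In T cells, interferon response genes were higher as a set (29 of 32, median 0.78, 7.37e-09, adjusted p = 0.671 with an estimated correlation) and complex I genes in 36 of 36 (median 0.63, 3.31e-11, adjusted p = 0.671 with an estimated correlation). Their proximal tubule transporter transcripts were lower in 22 of 23 (median -1.27, 7.37e-09, adjusted p = 0.671 with an estimated correlation; 0.129 without wild-type library 2), and macrophage markers higher in 10 of 10 (median 3.19, adjusted p = 0.646 with an estimated correlation). The lipid carrier Apoe, abundant in macrophages, measured 136 ± 31.2 against 27.8 ± 7.29 CPM but did not pass (edgeR adjusted p = 0.755). In B cells, cell cycle genes were lower in 14 of 14 (median -0.98, 0 past the gene test and 1 adjusted over the list alone, 2.30e-06, adjusted p = 0.629 with an estimated correlation), and the list missed without wild-type library 2 (adjusted p = 0.406). The B cell class joined 2 clusters that the libraries filled unevenly: one held 29 of 175 and 188 of 366 B cells in the mutants and 53 of 223 and 834 of 898 in the wild types, so changes within the class mix B cell subsets. Complex I genes were higher in 35 of 36 B cell members (median 0.58, 1.52e-11, adjusted p = 0.629 with an estimated correlation). So were macrophage markers in 8 of 9 (median 1.23, camera adjusted p = 1.60e-05) and dendritic cell markers in 3 of 5 (median 0.94, 0.00302), each with adjusted p = 0.311 with an estimated correlation. Of 31 lists in T cells 11 were higher and 1 lower, and of 29 in B cells 12 and 1.

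Transcripts of the mitochondrial genome, whose translation needs the mutated transfer RNA, were compared as shares of UMIs. With 2 libraries per group the smallest exact permutation p is 0.333, so this test could not call a difference of any size. In the proximal tubule the share was 12.7 ± 6.26% against 12.5 ± 1.24%, in the thick ascending limb 19.4 ± 5.61% against 17.7 ± 4.71%, and in the distal convoluted and connecting tubule 20.9 ± 6.13% against 16.4 ± 7.1%. T cells had 3.32 ± 0.505% against 3.64 ± 0.543%, B cells 3.56 ± 1.45% against 3.91 ± 0.380%, and monocytes 2.46 ± 0.555% against 3.20 ± 0.674%. Each difference except that of monocytes was smaller than the larger SD between libraries, and exact permutation tests gave p of 0.667 to 1. The difference changed sign with a library left out in every class but monocytes. It ran from -4.25 percentage points (without mutant library 2) to 4.59 (without mutant library 1) in the proximal tubule, and from -0.472 (without wild-type library 2) to 9.57 (without wild-type library 1) in the distal convoluted and connecting tubule. The proximal tubule share mixes clusters that differ in it. One with a median of 0.573% per cell held 702 of 2644 and 167 of 1245 tubule cells in the mutants. In the wild types it held 354 of 1688 and 313 of 3759. Another, with a median of 26.6%, held 255 and 320 cells in the mutants and 334 and 530 in the wild types. As a list, mitochondrial mRNAs were lower in monocytes (11 of 13 negative, median -0.25, camera adjusted p = 0.0348, adjusted p = 0.600 with an estimated correlation; 0.739 without wild-type library 2). No mitochondrial gene passed the edgeR test in any of the 6 classes. mt-Nd6 (ENSMUSG00000064368, chromosome M, 13552 to 14070), which codes for a complex I subunit and lies beside the TrnE gene (14071 to 14139) on the same strand, had log2 fold changes of -2.07 to -1.16 in the 6 classes (adjusted p 0.152 to 0.968). mt-Nd3 (ENSMUSG00000064360, chromosome M, 9459 to 9806), another complex I subunit, had -1.52 to -0.59 (adjusted p 0.142 to 0.968).

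As a share of mitochondrial mRNA UMIs over all cells, a measure chosen after the gene tests were seen, mt-Nd3 stood at 0.709 ± 0.115% in the mutants and 1.67 ± 0.892% in the wild types. The groups did not overlap in any of the 6 classes, which a single class shows by chance at p = 0.333 in the exact permutation test, and the classes share libraries. For mt-Nd6 the share was 0.031 ± 0.010% against 0.132 ± 0.130%, with 0.024% and 0.038% in mutant libraries 1 and 2, 0.039% in wild-type library 1 and 0.224% in wild-type library 2. The mt-Nd6 groups overlapped in T cells, B cells and monocytes, where wild-type library 1 stood at 0.031%, 0.023% and 0.026%. Over all cells, without wild-type library 2 the difference was -0.009 percentage points for mt-Nd6 and -0.332 for mt-Nd3, and without wild-type library 1 it was -0.193 and -1.59.

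**Figure D4:**
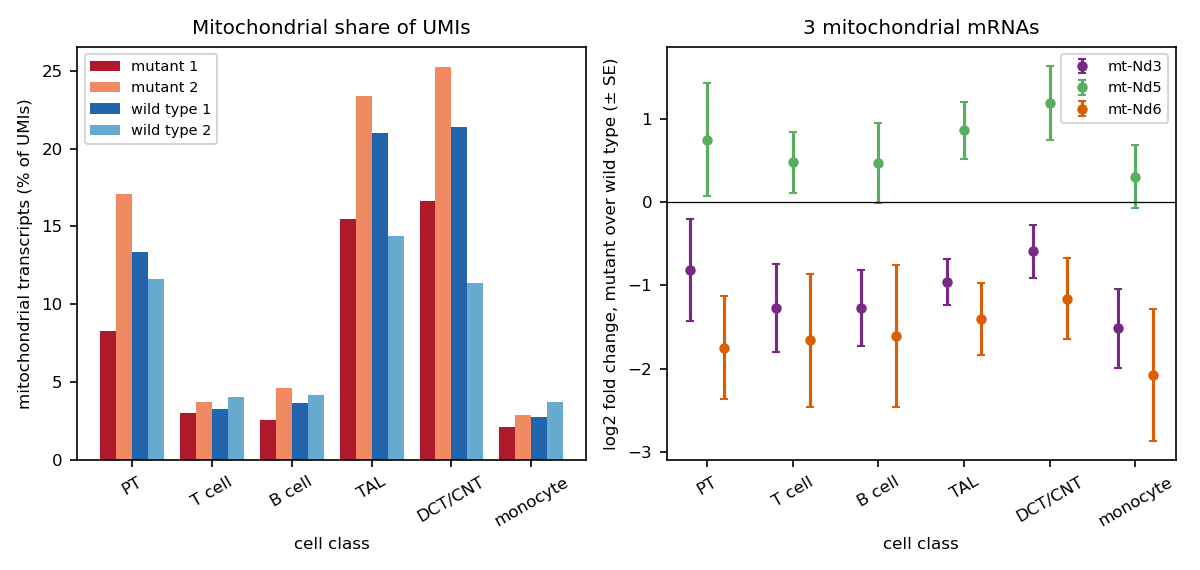
Left, mitochondrial transcripts as % of UMIs (vertical axis) in the 6 tested classes (horizontal axis; PT proximal tubule, TAL thick ascending limb, DCT/CNT distal convoluted and connecting tubule), bars being single libraries. Right, log2 fold change ± SE of 3 mitochondrial mRNAs in the same classes; mt-Nd6 ran from -2.07 to -1.16.

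The difference between the changes in the proximal tubule and in T cells, the pair of tested classes with the most cells in their smallest library, was tested as an interaction with the library as a block. 2 of 14516 genes passed in edgeR. Both the T cell side and the proximal tubule side mix subsets that the libraries filled unevenly. Egr1, an immediate early transcription factor, rose in the proximal tubule (log2 fold change 2.82, edgeR adjusted p = 0.0434) and was at -0.31 in T cells (difference -3.32, SE 0.47, adjusted p = 0.0268). Mctp1, a calcium-binding membrane protein, did not pass in either class alone (2.35 in the proximal tubule, edgeR adjusted p = 0.0718, and -1.53 in T cells, adjusted p = 0.755; difference -3.97, SE 0.58, adjusted p = 0.0268); it is named as 1 of a count of 2. Without wild-type library 2, Egr1 did not pass in the proximal tubule (log2 fold change 5.08, edgeR adjusted p = 0.233). With library totals, or at a mitochondrial share of at most 80%, 0 genes passed (edgeR, 550 and 620 at an unadjusted p under 0.05). Without single libraries 15 to 153 genes passed: 153 without mutant library 1, 28 without mutant library 2, 152 without wild-type library 1 and 15 without wild-type library 2.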

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

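The explanations below were tested after the patterns were seen, with each prediction written before its own test was run. Egr1 and Mctp1 stood out because their change differed between the proximal tubule and T cells in the interaction test of edgeR. The change in T cells minus that in the proximal tubule was -3.32 for Egr1 and -3.97 for Mctp1 on the log2 scale (adjusted p = 0.0268 for each, SE 0.47 and 0.58). In T cells Egr1 measured 22 and 18 CPM in the mutants and 8.79 and 48.6 CPM in the wild types, so the wild types lay on both sides. Mctp1 measured 7.65 and 12 CPM against 24.5 and 40.7 CPM in T cells, and 4.78 and 3.23 CPM against 0.921 and 0.900 CPM in the proximal tubule. Its level in the pooled immune classes was 128 CPM.

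Of the genes higher in mutant proximal tubule, 78.7% were dominated by the immune classes, against 6.94% of all genes tested, which is consistent with RNA from immune cells, free or in doublets. In the mutants, the 5% of tubule cells with the most macrophage-marker UMIs held 55.1% of these UMIs, between the bounds of over 60% for doublets and under 30% against them. By library, these cells held 61.2% and 35.4% in mutant libraries 1 and 2 and 38.7% and 31.2% in the wild types. Free RNA spread by depth would give 24.7% and 22.6% in the mutants and 21.1% and 24.5% in the wild types. Each library lay above that, and mutant library 1 alone passed 60%. In wild-type library 2, where macrophages made up 0.906% of cells, 52.3% of tubule cells held such a UMI. The markers together reached 202 CPM in its tubule cells, of which C1qa, C1qb and C1qc gave 8.14 CPM. UMIs made by the tubule cells themselves could thus be among those counted. The comparison therefore cannot weigh free RNA against doublets, and how many of these UMIs came from doublets stays open. The ratio of macrophage-marker CPM in tubule cells to the macrophage share of cells differed 8.54-fold between libraries, through wild-type library 2 alone (223 against 27.8, 27.7 and 26.1), again between the bounds. For C1qa, C1qb and C1qc, looked at after that result, the ratios were 15.8 and 9.43 in the mutants and 5.73 and 8.98 in the wild types, and their CPM ranked the libraries as the macrophage share did, so more immune cells in the mutants stay an open explanation. Immune genes expressed by tubule cells themselves stay open and untested.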

How the results depend on the processing

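The alternatives for single clusters, the shallow cluster, immune-dominated genes and the crossed block were chosen after seeing the data, as were the tests of macrophages, dendritic cells and endothelium. No result changed direction among the 47 named genes past the threshold. Over alternatives other than leaving out a library, their calls held in 364 values and were lost in 161, and with a library left out in 116 and 72. Calls held for 4 of the 47 with doublet calls kept, 7 with library totals, and 46 with the replicate block. With library totals the median log2 fold change of all genes lay at -0.171 to -0.258 in the 6 classes, against -0.032 to 0.020 with TMM.

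Genes past the threshold in the proximal tubule numbered 99. They became 0 with library totals only (edgeR, 1225 at an unadjusted p under 0.05, DESeq2 144), 475 with no filter on low counts, 266 with the replicate block, 1 with doublet calls kept, 158 at 1500 UMIs per cell, 64 with mitochondrial genes left out, 63 without the shallow cluster and 3 with immune-dominated genes left out. Single clusters gave 41 (cluster 2), 0 (cluster 5, edgeR, 392 unadjusted), 27 (cluster 6), 53 (cluster 7), 60 (cluster 12) and 2 (cluster 14). T cells went from 0 to 13 with DESeq2 and 141 with no filter, and B cells from 0 to 1 and 72. The thick ascending limb went from 39 to 8 with library totals, 489 with no filter, 66 with the block, 68 and 9 at mitochondrial shares of at most 25% and 80%, and 3 with doublets kept. The distal convoluted and connecting tubule went from 2 to 1 with RLE, 6 with totals, 4 with DESeq2, 69 with no filter, 4 with the block, 1 without immune-dominated genes, and in edgeR 0 with doublets kept, at 1500 UMIs or with mitochondrial genes left out. Monocytes went from 1 to 2 with DESeq2, 69 with no filter and 75 with the block. The crossed replicate block gave 275, 35, 1, 77, 63 and 28 calls in the 6 classes. The interaction count of 2 became 0 with totals and 0 at a mitochondrial share of at most 80% (edgeR, 550 and 620 at an unadjusted p under 0.05). The cause was not tested for any of these counts.

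Lists past the threshold became 0 with an estimated correlation in each of the 6 classes, and with fry 1 in the proximal tubule and 0 in the other 5. Marker lists past it (6, 4, 5, 0, 2 and 3) became 0 with either. The cause was not tested.

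With each library left out, the lone library of an arm being assumed to vary like the pair in the other, counts ranged 0 to 1181 (proximal tubule), 0 to 15 (T cells), 0 to 468 (B cells), 20 to 839 (thick ascending limb), 0 to 327 (distal convoluted and connecting tubule), 18 to 38 (monocytes) and 15 to 153 (interaction). Classes differing in share ranged 0 to 6. Lists ranged 16 to 23, 12 to 18, 11 to 15, 12 to 17, 7 to 11 and 11 to 16, and marker lists 6 to 11, 2 to 9, 5 to 8, 2 to 7, 0 to 5 and 2 to 4. The cause was not tested. Differences in mitochondrial share moved by less than the larger SD between libraries under the other settings. With a library left out they must do so, since each group has 2 libraries, so that bound says nothing there. They changed sign with a library left out in 5 of the 6 classes. The 4 libraries can be split 3 ways, too few for a share under 0.05: the highest other split gave 0 calls against 99, 39, 2 and 1 in the tubule classes and monocytes, and 4 against 0 in B cells. At this depth 2-fold changes were found in 4% to 39% of simulated genes.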

Other observations

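The explanations here were tested after the patterns were seen, and macrophages, dendritic cells and endothelium were tested after the data were seen. Ccl7 (ENSMUSG00000035373, chromosome 11, 82045712 to 82047525), a chemokine that draws monocytes out of the blood, rose in mutant macrophages. It measured 147.7 and 81.94 CPM in the mutants and 7.91 and 17.2 CPM in the wild types (log2 fold change 3.88, SE 0.52, adjusted p = 0.0326 by edgeR). It was the single gene of 12441 to pass, and DESeq2 called 3. Without mutant library 2, 0 genes passed (edgeR, 256 at an unadjusted p under 0.05), with 2 without mutant library 1, 340 without wild-type library 1 and 49 without wild-type library 2. Wild-type library 2 held 57 macrophages. A macrophage cluster with Ccl7 among its 10 most raised genes held 627 of 2759 and 592 of 1719 mutant macrophages and 89 of 809 and 16 of 57 wild-type ones, so the change within the class mixes subsets.

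In dendritic cells 0 of 11666 genes passed (edgeR, 571 at an unadjusted p under 0.05, DESeq2 2), and in endothelium 0 of 11467 (edgeR, 344 at an unadjusted p under 0.05, DESeq2 3). Lrg1, an inflammatory glycoprotein of endothelium, measured 160.8 and 221 CPM against 26.4 and 28.6 CPM but did not pass (log2 fold change 2.91, adjusted p = 0.502 by edgeR). Cxcl10, an interferon-induced chemokine, measured 74.8 and 112 CPM in mutant and 12.7 and 22.1 CPM in wild-type dendritic cells and did not pass (log2 fold change 2.83, adjusted p = 0.182 by edgeR). Both were chosen after their values were seen. Without wild-type library 1, 444 and 397 genes passed in dendritic cells and endothelium, and without wild-type library 2, 10 and 2. Without mutant library 1 the counts were 28 and 4, and without mutant library 2 they were 50 and 12.

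Pappa2, Robo2 and Nos1, singled out after their values were seen, were higher in mutant thick ascending limb (Nos1: 27 and 30 UMIs against 0 and 0, adjusted p = 0.00957 by edgeR). Nos1 and Pappa2 UMIs fell in the same mutant cells, with 9 cells holding both, 4 Pappa2 alone and 0 Nos1 alone (odds ratio 1037, approximate interval 52.0 to 20671). A candidate explanation is a small set of macula densa cells, more of them captured in the mutants. Wild-type cells outside the class held 0.146 of the Pappa2 UMIs per total found in all mutant cells, 25 UMIs in wild-type library 2 and 1 in wild-type library 1, which lies between the bounds set and leaves open whether some wild-type macula densa cells were placed in another cluster. Whether the mutation adds such cells or the dissociation released them unevenly was not tested.

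In the 5 of 6 tested classes where nuclear genes of complex I were higher, random lists matched on gene length and level reached at least 0.57 of the complex I median (0.88 in the proximal tubule, 0.75 in T cells, 0.62 in B cells, 0.83 in the thick ascending limb, 0.57 in monocytes). No matched list was as high in T cells, B cells or monocytes. The random lists left out only the complex I genes. They could draw other respiratory and ribosomal protein genes, such as the mitochondrial ribosomal ones, higher in 76 of 78 in the proximal tubule. The ratios therefore cannot separate a shift between short and long genes from a joint rise of such genes. That shift stays a candidate explanation. Without wild-type library 2 the complex I median kept over 2 parts in 3 of its size in 2 classes (0.805 of it in B cells and 0.91 in the thick ascending limb), and 0.66 in monocytes, 0.618 in T cells and 0.157 in the proximal tubule. At the preset correlation the list still passed camera without that library in these classes other than the proximal tubule (adjusted p = 8.02e-06, 0.00011, 5.68e-05 and 7.17e-05), but not in the proximal tubule (0.769), and with all libraries an estimated correlation ended the call in each of the 5 (0.416 to 0.723), so that library as the cause stays open. A response of the nucleus to the mitochondrial defect was not separated from these.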
